A study of Rattus norvegicus with 21 samples.

How the data were processed

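Total RNA from areas of the dentate gyrus was measured on Illumina rat expression beadchips, in which beads carry probes and the brightness of each probe reports its transcript. Per the labels, the areas came from hippocampal slices of Wistar rats that had been given pilocarpine to induce epilepsy, after electrophysiology in the slice had sorted areas into those that generated fast ripples (FR) and those that did not (nonFR). Per the labels' protocols, RNA was purified on spin columns and labelled with biotin. The labels gave 21 arrays, 10 of FR areas and 11 of nonFR areas, from 11 slices of 6 animals named P91, B9, B1, B3, B13 and B10. In 10 slices both areas were measured, and 1 slice of B9 gave a nonFR area only. The labels name no chip or position on a chip, sex or age, and no chip entered any fit.

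The deposited table per probe gave, per the file headers, an average signal and a detection p for each array. The signals were taken as intensity on a linear scale without background correction or normalization, as the deposited values showed, and whether any step came before them was not given in the sources used here. The detection p-value, deposited beside each signal, states how likely a signal as bright would be among the array's negative controls. The second deposited table held the authors' processed values on a log2-like scale, and the submitters' processing notes name lumi 2.2 as the tool. Their ranks within each array equalled those of the signal (Spearman correlation 1 on each array), and the column medians lay between 6.73 and 6.76, so the columns had been brought to a similar distribution. The exact transformation, its log base and any background step stay unknown, and those values were used only as an alternative. Each detection column correlated with the signal column of its own array between -0.99 and -0.95 (Spearman), more strongly than with any other array's signal.

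The table held 22523 probes. Of these, 720 were 0 in every column of signal, detection p and processed value and were dropped, which left 21803. Over the whole table, the platform annotation gave 1 gene symbol to 13793 probes, several symbols to 0, and none to 8730, which are unnamed here. Of the annotated probes, 13752 were found by gene number in the RefSeq gene table of assembly GRCr8, which changed 0 symbols. No genome build is tied to the deposited values, so no coordinates are given. No sample column was left unused.

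Signals were background-corrected by the normal-exponential method of limma 3.58.1 in R 4.3.3 (neqc, which takes the negative-control distribution from the detection p-values), with an offset of 16, quantile-normalized and put on a log2 scale. The offset compresses differences of dim probes, so folds of genes near background are understated. Probes with a detection p below 0.01 on at least 10 arrays were kept, 8223 or 37.71% of those measured. For each symbol the probe with the highest mean was used, giving 8211 features, of which 6347 had a symbol and 1864 did not. Only 8 genes had more than 1 kept probe. The probes of Actb, Eef1a1, Ilk, Rps9 and Txn1 repeated each other's values. Those of Aprt differed in size (0.24 and 0.0089 log2), and those of Gstp1 and Higd2a differed in sign (0.092 and -0.070, and -0.015 and 0.25 log2).

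The comparison of FR with nonFR areas was fitted with limma (lmFit and eBayes) over all 21 arrays, with the animal as a block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pairing rests on the labels, since areas of one animal share that animal. The deviations from the group means correlated on average by 0.36 between both areas of a slice (10 pairs, from -0.018 to 0.64), by 0.35 between areas of different slices of an animal and by -0.11 between animals. No arrays were identical. Areas and slices of an animal are not independent animals, and the animal block leaves their shared slice unmodelled, so the fit with slices as blocks and the fit on animal means stand among the alternatives. Two-sided p-values of single genes come from this fit unless another test is named.

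Fixed before the data were examined were 45 lists of genes, of functions and of cell types, together 1140 genes. Of these genes 919 had a probe with that name and 599 were tested. The 39 lists with at least 5 tested genes were compared with all other genes by camera, with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided sign-flip test over the 6 animal means of each list, whose smallest possible p is 0.0313. The lists for HCN channels, CA1 pyramidal cell, choroid plexus and ependyma, thalamus and neighbouring regions, red blood cell and lymphocyte had 1, 1, 2, 4, 1 and 1 tested genes and were not compared. The list of Kv potassium channels spans the family, but interest in that family in these samples was known beforehand, so its members are not independent evidence. The agreement of animals was the mean Pearson correlation, over genes, of the FR minus nonFR differences of animal means between the 15 pairs of animals, set against the 32 distinct exchanges of the labels within whole animals.

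Genes are named by a rule fixed at the same time. It takes up to 12 genes with the largest change in each direction among those past the threshold with the same sign in at least 5 animals. Where fewer than 8 pass in a direction, it takes the genes with the lowest unadjusted p and the same sign in at least 5 animals, up to 8, as values that did not pass. From a list past its threshold it takes the 4 members with the lowest p, from other lists described up to 2, and as a check of the tissue Prox1, Gad1, Gfap, Aif1, Mbp, Npy, Bdnf and Fos.

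The procedure was tested on simulated data made from the means and spreads of the 8211 features, with 200 of them changed by known folds. Of 50 genes changed per fold, it called 30 at 1.5-fold, 43 at 2-fold, 48 at 3-fold and 50 at 4-fold, with 13 calls among unchanged genes. With the same changes added to the real arrays, it called 32, 44, 48 and 50, with 0 calls among the other genes. Each added change had the same size on every FR array, and the simulated noise was independent between genes. Changes that vary between animals were not simulated, so the counts do not tell how often those would be called. Of the unchanged genes, 4.4% had an unadjusted p below 0.05 in limma on the simulated values and 0.35% on the real arrays. Alternatives covered the background correction and normalization, the processed values, the detection filter, the choice of probe, the block, moderated variances, array weights and each animal left out. The log2 mean signal as a covariate and the removal of the dimmest array were added after seeing the data.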

Results

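Fast ripples are brief, very fast field oscillations recorded in epileptic hippocampus. The series asked how gene expression in areas of the dentate gyrus that generate them differs from that in nearby areas that do not, in slices from rats made epileptic with pilocarpine, a muscarinic agonist that triggers status epilepticus. The 10 FR areas came from 2 slices of P91, 2 of B9, 1 of B1, 2 of B3, 1 of B13 and 2 of B10, and the 11 nonFR areas from the same slices and 1 more of B9. Mean probe signal ranged from 101.3 to 369.8 in FR areas (184.9 ± 82.9, SD, n = 10) and from 84.2 to 310.9 in nonFR areas (215.2 ± 88.0, SD, n = 11). Probes detected at p below 0.01 numbered 8023 ± 910 in FR and 8120 ± 1114 in nonFR areas (SD), with the fewest, 5648, in a nonFR area of B10.

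The tissue markers were measured in both kinds of area without a difference past the threshold. Gfap, the intermediate filament of astrocytes, had a log2 value of 12.36 ± 1.32 in FR (SD, n = 10) and 12.33 ± 1.30 in nonFR areas (SD, n = 11). Gad1, which makes GABA in interneurons, stood at 10.77 ± 0.78 and 10.80 ± 0.999, and Aif1, a microglial calcium-binding protein, at 8.10 ± 0.76 and 7.82 ± 0.61. The neuropeptide gene Npy stood at 7.66 ± 1.06 and 7.61 ± 0.66. Bdnf, a neurotrophin induced by activity, was 0.45 log2 lower in FR areas (SE 0.41, p = 0.288), and Fos, an early marker of neuronal activity, was 0.33 higher (SE 0.41, p = 0.43). The probes for Prox1, the granule cell transcription factor, and Mbp, a myelin protein, gave values of 5.85 and 5.95 in FR areas, below the median of tested genes on every array (6.50 to 6.52). The adjusted p in limma was 0.9996 for each of these 8 genes. A p that misses the threshold does not show that values did not differ.

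No gene passed the threshold in the comparison of FR with nonFR areas. Of 8211 features tested with limma, 0 had an adjusted p below 0.05, the smallest adjusted p being 0.9996. At an unadjusted p below 0.05 there were 28, 12 higher and 16 lower in FR areas, where chance alone would give about 411. The median size of the fitted difference was 0.057 log2, the largest was 0.89, and 0 features differed by more than 1. For 7934 features (96.6%) the 95% interval of the difference in this fit lay within 1 log2 unit, a 2-fold change, in either direction. That interval treats areas of an animal as replicates and leaves out how the difference varies between animals. It therefore does not exclude 2-fold changes over animals. RT1-Db1, for example, had an interval of -0.14 to 0.77 but a difference of 2.84 in B13 (SD 1.15 over animals, n = 6). The same sign in 6 of 6 animals was seen for 104 features (1.27%, chance 3.125%), 52 in each direction.

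The genes given next, higher and lower, did not pass. The rule took them by lowest unadjusted p among genes with the same sign in at least 5 animals. That agreement was a condition of choice and is not evidence of its own. The higher values in FR areas included a glial and a microglial gene. Tfb2m (probe ILMN_1368392), a mitochondrial transcription factor, had the smallest p, 0.00129, with 7.50 ± 0.47 in FR and 7.10 ± 0.24 in nonFR areas (SD, n = 10 and 11). It was 0.39 log2 higher (SE 0.098) and higher in 5 of 6 animals. Sox10, a transcription factor of the oligodendrocyte lineage, was 0.39 higher (SE 0.15, p = 0.0167), and Lcp1, an actin-bundling protein of white blood cells and microglia, was 0.54 higher (SE 0.25, p = 0.0440), both in 5 of 6 animals. Lcp1 was 2.51 higher in B13, and without that animal the fitted difference was 0.33. Sh3kbp1, an endocytic adaptor, and Pomc, the precursor of corticotropin and beta-endorphin, were 0.31 and 0.11 higher, each in 6 of 6 animals. N6amt1, a methyltransferase, Gtf2e1, a general transcription factor, and Acot13, an acyl-CoA thioesterase, were 0.25, 0.12 and 0.35 higher in 5 of 6 animals.

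The lower values in FR areas included a potassium channel subunit and a neuropeptide. Kcnv1 (probe ILMN_1367375), the electrically silent Kv8.1 subunit that modifies Kv2 channels, stood at 6.05 ± 0.20 in FR and 6.29 ± 0.29 in nonFR areas (SD, n = 10 and 11). The difference of -0.24 log2 (SE 0.091, p = 0.0173, adjusted p 0.9996 in limma) had the same sign in 6 of 6 animals, though it was only -0.0078 in B9. Cartpt, the precursor of the CART peptides, had a difference of -0.50 log2 (SE 0.21, p = 0.0282), in 5 of 6 animals. Arl6, a small GTPase of primary cilia, and Gpr22, an orphan receptor, had differences of -0.61 and -0.38, each negative in 5 of 6 animals, with B13 the furthest at -2.28 and -1.61. Without 1 animal, the fitted value of 82 of the 103 genes chosen by the naming rule moved by over 1.5 times. Dnmt1, the maintenance DNA methyltransferase, had -0.23 with the same sign in 6 of 6 animals. Eftud2, a spliceosomal GTPase, Rnf167, a ubiquitin ligase, and the zinc finger gene Zfp638 had -0.26, -0.19 and -0.24.

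**Figure D1:**
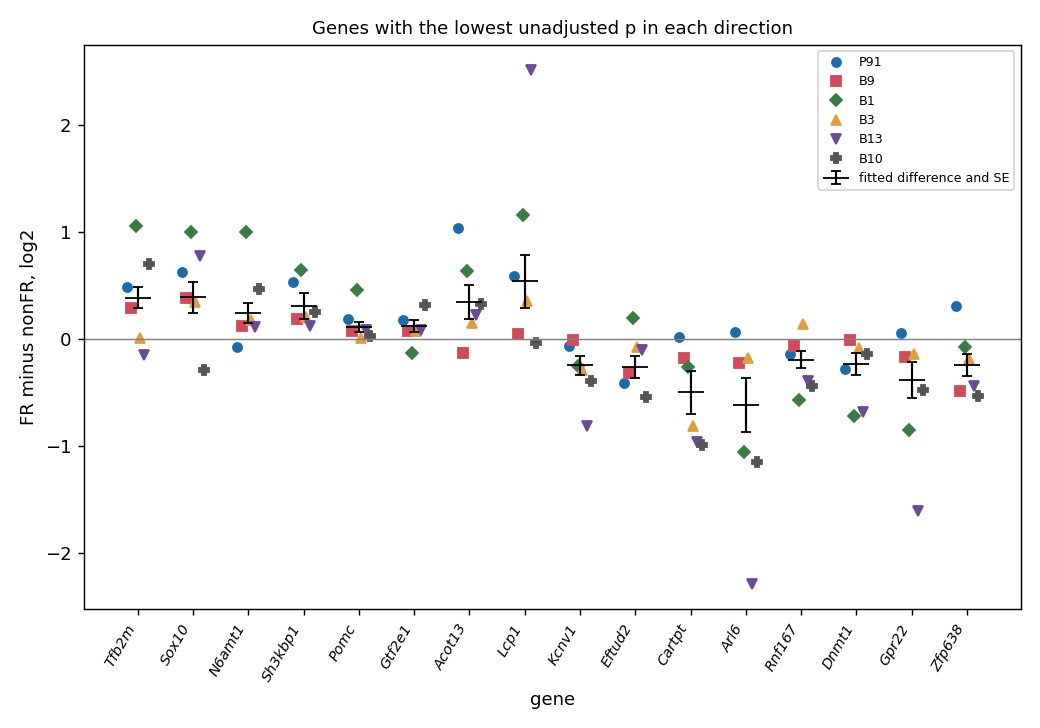
FR minus nonFR difference (log2, y axis) of 8 genes in each direction (x axis), with 1 symbol per animal for the difference of its means. A black bar gives the fitted difference with its standard error. The genes have the lowest unadjusted p among those with a symbol and the same sign in at least 5 animals. Agreement of most animals was therefore a condition of choice. None passed the adjusted threshold, and single animals lie far from the rest, such as B13 at -2.28 for Arl6.

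Over all genes, the differences did not run the same way from animal to animal. The mean correlation across genes between the 15 pairs of animals was -0.065, and 27 of the 32 exchanges of the labels within animals gave a value as high (exact one-sided p = 0.844). Single pairs ranged from -0.59 between P91 and B9 to 0.25 between B1 and B3, and 8 of the 15 were below 0. Genes are not independent replicates, and these correlations describe pairs of animals. Slices of the same animal did not share a difference either. In the 4 animals with both areas in a pair of slices, the FR minus nonFR differences of the slices correlated by -0.25 on average, from -0.50 to 0.042.

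Of the 39 gene lists, 4 had members that stood higher in FR areas than other genes by camera with its preset correlation. The oligodendrocyte markers had a median difference of 0.23 log2 (adjusted p 0.0055), the genes of antigen presentation and interferon response 0.14 (0.0055), the subunits of oxidative phosphorylation 0.082 (0.0055), and the genes of the adenosine system 0.087 (0.0432). With an estimated correlation the adjusted p = 0.878 for each of the 4, and fry gave an adjusted p of 0.968 for each of the 39 lists. The exact sign-flip test over 6 animals gave p = 0.219, 0.219, 0.219 and 0.375 in that order, its smallest p over the 39 lists being 0.125 (0.923 after adjustment). No member of any list passed over all genes or when adjusted over the list alone. Without P91 the preset test called 0 lists, without B9 8, without B1 2, without B3 2, without B13 1 and without B10 10. With 1 animal left out, the medians of the 4 lists ran from 0.13 to 0.34, 0.044 to 0.18, 0.045 to 0.13 and 0.043 to 0.098 in the same order, the lowest being without P91, B13, B10 and B13.

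The oligodendrocyte list, genes for myelin and its upkeep, had 12 of 12 tested members higher in FR areas, though not all clearly so. Mbp was only 0.0036 log2 higher (SE 0.053) and kept that sign in 2 of 6 fits with 1 animal left out. Mal, a myelin proteolipid, was 0.31 log2 higher (SE 0.18, p = 0.104), Gpr37, an orphan receptor, 0.17 higher in 6 of 6 animals, Tf, transferrin, 0.39 higher (SE 0.33), and Mog, a myelin surface glycoprotein, 0.33 higher (SE 0.31). Without B13, Tf was 0.13, Mal 0.21 and Mog 0.17 higher. The list mean was 0.33 ± 0.47 over animals (SD, n = 6), with 0.94 in B13, 0.71 in B1, 0.55 in P91, 0.12 in B3, -0.15 in B9 and -0.17 in B10. The list of oligodendrocyte precursors, with Sox10 and Olig1, a lineage transcription factor (0.41, SE 0.39), had a median of 0.17 and an adjusted p of 0.0733, with 5 of 6 members higher.

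In the list of antigen presentation and interferon response, 19 of 24 members were higher in FR areas, led by genes of the major histocompatibility complex. RT1-A1, a class I gene, was 0.33 log2 higher (SE 0.17, p = 0.0754), and the class II genes RT1-Ba, RT1-Da and RT1-Db1 were 0.34, 0.72 and 0.32 higher. Animal B13 set the class II values. There RT1-Da was 5.07 log2 higher in the FR area, RT1-Db1 2.84 and RT1-Ba 2.43, against 1.06, 0.21 and 0.26 in the next animal. The list mean was 0.25 ± 0.38 over animals (SD, n = 6). Beside it, microglia and macrophage markers had a median of 0.13 (11 of 14 higher, adjusted p 0.131), and complement genes a median of 0.13 (10 of 12 higher, adjusted p 0.373). Both lists were highest in B13, at 1.12 and 1.17. Aif1 was 0.31 higher (SE 0.25), and P2ry12, a purinergic receptor of microglia detected on only 12 arrays, 0.053 higher. The complement inhibitor Serping1 was 0.32 higher (SE 0.30), and the protease C1r had -0.17 (SE 0.15). Without B13, Serping1 was 0.076, RT1-Da 0.25, RT1-Ba 0.12 and RT1-Db1 0.049 higher.

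Of the subunits of oxidative phosphorylation, 37 of 45 were higher in FR areas. Ndufb7 of complex I was 0.32 log2 higher (SE 0.21, p = 0.144), Cox5b of complex IV 0.20 higher in 6 of 6 animals (SE 0.13), and Atp5f1c and Atp5me of the ATP synthase 0.10 and 0.21 higher. The list mean was highest in B10 (0.34) and below 0 in B9 (-0.055) and B3 (-0.093). With array weights its median turned to -0.040, and without the dimmest array its adjusted p was 0.224. In the adenosine system, 9 of 10 members were higher. Nt5e, which makes adenosine from AMP, was 0.10 higher (SE 0.069), the receptors Adora2b and Adora2a 0.072 and 0.13, and Adk, which clears adenosine, 0.18 (SE 0.15). The mean of this list was 0.53 in B13 and -0.16 in B1.

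**Figure D2:**
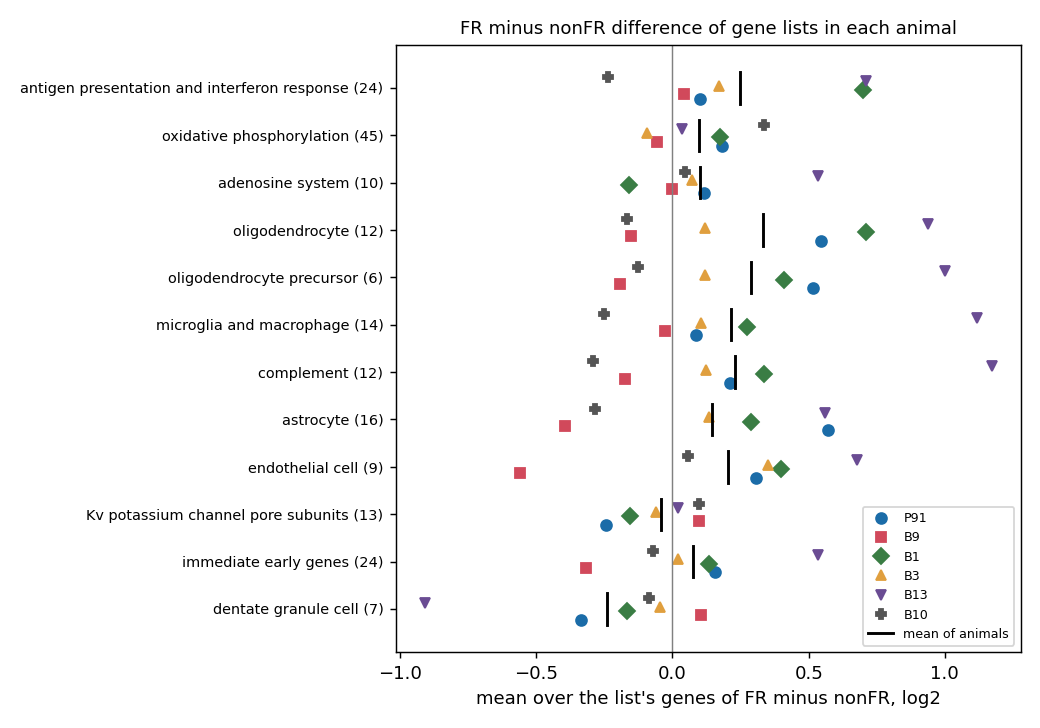
Mean FR minus nonFR difference (log2, x axis) over the tested genes of 12 lists (y axis, number of genes in brackets), with 1 symbol per animal and a black line at the mean of the 6 animals. The glial and immune lists are high in B13 and below 0 in B10 except for endothelial cells, and the granule cell list is at -0.91 in B13.

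Ion channel and synaptic lists did not pass. Of 13 Kv potassium channel subunits, 8 were higher and 5 lower, with a median of 0.012 (adjusted p 0.703). Besides Kcnv1, Kcnd1, the Kv4.1 subunit, had -0.27 (SE 0.16, p = 0.115). Kcna4, the Kv1.4 subunit, was detected on 8 arrays and so was not tested. It is named after its value was seen, and without the detection filter it stood at -0.20 (SE 0.10, p = 0.0742) and was lower in 5 of 6 animals. Other potassium channels had a median of 0.0057 (0.959), with Kcnk2, a two-pore channel, at -0.29 (SE 0.32) and Kcnab2 at 0.039. Sodium channels had -0.023 (0.968), with the beta subunit Scn2b at 0.058 and Fgf13 at -0.41 (SE 0.31). Calcium channels had -0.049 (0.506), with 9 of 11 lower, Cacng2 at 0.36 (SE 0.30) and Cacnb2 at -0.28 (SE 0.26). GABA-A receptor and scaffold genes had -0.0026 (0.929), with Gabrg1 at 0.042. Ionotropic glutamate receptors had -0.038 (0.929), with the kainate subunit Grik2 at -0.35 (SE 0.21). Metabotropic receptors and the postsynaptic density had -0.036 (0.506), with Grm2 at -0.41 (SE 0.30), and synaptic vesicle genes -0.043 (0.731), with Synpr at -0.24 (SE 0.14). Neuropeptides and their receptors had -0.022 (0.929), with Cck, cholecystokinin, at 0.71 (SE 0.48) and Sstr2 at 0.21 (SE 0.15).

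Lists of neuronal activity and growth had medians near 0. Immediate early genes had -0.0088 (adjusted p 0.929), with 11 of 24 higher, and activity-regulated trophic factors -0.0027 (0.929), with Plat, tissue plasminogen activator, at 0.47 (SE 0.26, p = 0.0884). Genes of axon growth had 0.011 (0.953), of extracellular matrix and perineuronal nets 0.0084 (0.929), and of inflammatory signalling 0.011 (0.953), where Il18 was at 0.17 (SE 0.090). Acan, the main proteoglycan of perineuronal nets, had -0.057 with the same sign in 6 of 6 animals. Astrocytic clearance genes had 0.018 (0.885), gap junctions 0.023 (0.929), with Tjp1 at -0.53 (SE 0.29), and chloride and sodium-potassium transport 0.019 (0.929). Ribosomal proteins had 0.066 (0.506), with 34 of 47 higher, and cholesterol biosynthesis 0.051 (0.373), with 12 of 15 higher. Heat shock and unfolded protein genes had -0.022 (0.708), glycolysis and hypoxia genes 0.049 (0.953), neuronal RNA-binding proteins -0.018 (0.506), histone deacetylases and DNA methylation -0.0028 (0.531) and apoptosis genes 0.037 (0.506).

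Among cell types, 5 of 7 granule cell markers were lower in FR areas, with a median of -0.028 and a mean of -0.17 (adjusted p 0.242). Calb1, calbindin, stood at 9.86 ± 1.32 in FR and 10.48 ± 1.58 in nonFR areas (SD, n = 10 and 11), a difference of -0.66 (SE 0.52), which was -3.32 in B13 alone and -0.38 in the fit without that animal. The list was lower in 5 of 6 animals and furthest from 0 in B13 (-0.91). Immature granule cells and progenitors had a median of 0.017 (0.929), mossy cells 0.013 (0.968), CA3 pyramidal cells 0.036 (0.929), interneurons 0.017 (0.456) and astrocytes 0.085 (0.506). Endothelial markers had 0.076 (0.257), with 9 of 9 members higher, and pericyte, smooth muscle and meningeal markers 0.058 (0.257), with Igf2, a growth factor, at 0.61 (SE 0.41). In 10 lists the median, the mean and the direction of the test differed in sign, and none of these passed. They are Kv and other potassium channels, sodium channels, GABA-A receptors, neuropeptides, immediate early genes, axon growth, extracellular matrix, gap junctions and mossy cells.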

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

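Of the tests in this part, those of granule cell share and of array brightness against the marker lists were chosen only after the result was seen. So were the test on members of the granule cell list, 2 spread checks and the use of the array splits for the low count, and each of the last 3 turned a reading against an explanation into an open one. In 247 sets of values of the text's genes and lists (10 FR arrays or 6 animals), 25 had 1 value set far apart from the others. Chance would give about 12.35 if the sets were independent. They share the same arrays and animals, so the count of 25 does not show an excess over chance. Animal B13 accounts for 13 of the 25, with 1 slice behind its values.

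In the FR area of B13, class II genes stood far above those of other animals. RT1-Da was at 5.07 log2 FR minus nonFR, RT1-Db1 at 2.84 and RT1-Ba at 2.43, and on the FR array of that animal RT1-Db1 had a level of 8.70 and RT1-Ba of 8.23. The same animal was highest for Sstr2 (1.32), Cntn2 (1.21) and Rab3c (0.33) and for the list of neuronal RNA-binding proteins (0.12). It was lowest for Bdnf (-2.82), Cacnb2 (-2.09), Nectin3 (-0.79) and Prox1 (-0.33). Animal B9 was highest for Klf2 (0.22) and Fxyd1 (0.48), and B1 lowest for the list of cholesterol biosynthesis (-0.48). Of single FR arrays, the first slice of P91 was highest for Adora2b (6.42), and the slices of B9 for Klf2 (6.34), Kcnab2 (6.10), Cacng2 (9.16) and Casp9 (7.87). The array of B1 was highest for Il18 (7.21), and an array of B10 was highest for Nectin3 (6.63) and lowest for Gfap (9.32). The brightest FR array, from B9, had a mean signal of 369.8 against 243.9 for the next.

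Glial, vascular and immune markers were higher in the FR areas of some animals and not of others. The mean of 6 such lists was 0.81 log2 in B13, 0.54 in B1, 0.37 in P91, 0.14 in B3, -0.14 in B10 and -0.25 in B9. A lower share of granule cells in the area taken may account for part of this. Over the 6 animals the granule cell list was lower where these lists were higher, with rho = -0.89 (exact permutation p = 0.0333, adjusted 0.0667) and r = -0.85 (exact p = 0.0153, adjusted 0.0306), while rho was -0.8 without B13, -0.8 without B9 and -0.9 without each of the others. Without both B13 and B9, r was -0.57 over the 4 animals left, and -0.80 for brightness. The size of the list value rests on Calb1 (-0.66) and C1ql2 (-0.47), while the other 5 members lie between -0.064 and 0.041, though those 5 alone gave r = -0.94. The lists of cell types did not move alike in B1. There the list of pericyte, smooth muscle and meningeal markers stood at 1.14 and the microglial list at 0.27. Its members Igf2 and Ptgds stood at 2.63 and 3.59 in B1, so the value does not speak for pericytes alone. It rests on 1 slice, whose FR minus nonFR brightness was -1.21 log2. A change within single cell types stays open. Array brightness gave rho = -0.26 (exact p = 0.658), which by its bound alone speaks against it, but in the later spread check rho was -0.8 without B13 and between -0.3 and 0.1 without each of the others. The count of lists shifted in FR areas by camera with its preset correlation was also 4 with brightness as a covariate, but with so few animals brightness stays open.

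The differences of P91 and B9 opposed each other over genes (r = -0.59). Removing array brightness within animals left r = -0.59, which by the bound set beforehand speaks against brightness. The FR minus nonFR brightness was small, though (-0.16 log2 in P91 and 0.14 in B9), so the removal could change little. The mean of B9 also hides slices of opposite sign, with FR against nonFR signals of 194.1 and 306.0 in S1 and 369.8 and 168.9 in S3. Brightness of single slices therefore stays open. Removing the mean of the glial and vascular markers left -0.42 over the genes outside those lists, which by the bound of -0.4 set beforehand speaks against cell types, but the later spread check gave -0.47 to -0.38 with each list left out of that mean, so this stays open. Only 1 of the 4 slice-by-slice correlations lay below -0.3, that of the S3 slice of P91 with the S1 slice of B9 at -0.63, and the others lay between -0.20 and 0.014. The opposition is therefore consistent with a part played by single slices.

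The number of features at an unadjusted p below 0.05 in limma, 28, lay far below the 411 expected on average if no gene differed. The 32 exchanges of the labels within animals gave from 28 to 759, with a median of 179 and 28 of them below 411, so counts below that level are usual in these arrays. The real labels gave the lowest, and 1 of 32 was as low, the next being 41. By the bound set beforehand this speaks against swings of differences shared by many genes, but 2 of 100 splits of the arrays, the real one included, were as low, the other giving 22, so the swings stay open. Probes near background are not behind it, since 0.37% of the brighter part of the genes had such a p and 0.32% of the dimmer part.

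Chance cannot be excluded for the gene lists. Of 100 splits of the 21 arrays, the real one included, 51 gave 4 or more lists, the highest other giving 15, and of the 32 exchanges within animals, which keep each pair parted, 17 did, the highest other again giving 15. For single genes the comparison decides nothing, since a count of 0 is reached by 100 of 100 splits whatever the data.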

How the results depend on the processing

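The covariate and the removal of the dimmest array were chosen only after the result was seen. The count of genes past the threshold was 0 under each of the 14 alternatives and with each of the 6 animals left out, in limma, while the count at an unadjusted p below 0.05 ranged from 10 to 554 and from 23 to 136. Of these, no replicate block gave 0 genes and 10 at that p, slices as replicate block 0 and 48, and animal means with the animal as replicate block 0 and 101. The 554 came without a detection filter, where far more than 8211 features were tested. The 411 expected for 8211 features is therefore not its measure, and 554 is not an excess over chance. The agreement of animals stayed between -0.092 and -0.031 under 10 alternatives and between -0.11 and -0.019 with each animal left out.

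The count of shifted lists, 4, moved to 0 without a detection filter, 2 with array weights, 7 with slices as replicate block, 10 on animal means with the animal as replicate block, 0 with an estimated correlation and 0 with fry, and with each animal left out it ran from 0 to 10. Without a replicate block it was 4. The smallest adjusted p ranged from 8.82e-07 to 0.968. Of 16 alternatives, the list of antigen presentation kept its call under 13, oligodendrocytes under 12, oxidative phosphorylation under 11 and the adenosine system under 10. With each animal left out, antigen presentation kept it in only 2 of 6 fits (adjusted p up to 0.186) and each of the other lists in 3 of 6. With the log2 mean signal as a covariate, added after seeing the data, there were 0 genes and 4 lists, and without the dimmest array, also added then, 0 genes and 6 lists. With array weights the median of oxidative phosphorylation turned to -0.040. The cause of these moves was not tested.

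Of 1442 values of 103 named genes, 7 changed sign. They are Mbp with median centring (-0.0053) and with the log2 mean signal as covariate (-0.0050), Ndufb7 (-0.025), Atp5f1c (-0.022), Gad1 (0.023) and Npy (-0.0021) with array weights, and Gad1 without the dimmest array (0.073). With 1 animal left out, 9 of 618 values changed sign, in 6 genes. Mbp ran from -0.017 to 0.046, Gad1 from -0.45 to 0.26, Npy from -0.11 to 0.29, Gfap from -0.041 to 0.32, Gja1 from -0.51 to 0.043 and Hopx from -0.026 to 0.21. No named gene passed the threshold under any alternative. A chip or position as a block was not run, since the array names carry none. Signal over background limits what was tested: 37.71% of probes were kept, and dim genes such as Kcna4 are outside the count.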

Other observations

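Of the tests in this part, the one on co-expression was reworded and rerun only after a first value had been seen, and the search for genes that part by animal was prompted by the differences between animals. The animals differed from each other far more than FR from nonFR areas did. In the same limma fit, 1072 of 8211 features (13.1%) differed between animals at an adjusted p below 0.05, against the spread between areas and slices of an animal, which are not independent animals. Complement genes led, with 7 of 12, followed by immediate early genes, with 11 of 24, and immature granule cell markers, with 3 of 7. Serping1, a complement inhibitor, had a mean log2 level of 10.44 in P91 and 6.54 in B10, C1qa, which starts the classical pathway, 9.70 and 6.62, and C4b 10.43 and 7.25. Fos stood at 10.34 in P91 and 6.55 in B3. Gfap was 13.48 in B9, 13.47 in P91 and 10.60 in B10. Penk, which encodes enkephalins, was highest in B9 at 10.31 against 6.91 in B3, and Il1b, an inflammatory cytokine, highest in P91 at 9.86 against 6.76 in B9. These genes were picked by their range after their values were seen. Arrays of an animal may have been processed together, and no label separates that from the animal. Array brightness also differed, with mean signals from 235.4 to 280.6 in P91 and from 84.2 to 126.9 in B10. Whether brightness bears on these levels was not tested. With slices grouped by animal, the median ratio of variation between to within animals was 2.21, above each of 20 random regroupings of the slices (highest 1.91).

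A few genes stood high in some animals and low in others. Tac3, which encodes neurokinin B, stood between 10.11 and 11.35 in P91, B9 and B3 and between 6.04 and 6.85 in B1, B13 and B10. Rps9, a ribosomal protein gene, stood between 9.30 and 10.00 in B9, B3 and B10 and between 5.90 and 6.17 in P91, B1 and B13, and an unnamed probe, ILMN_1365113, followed the same animals. Rps9 was detected on 21 of 21 arrays, so its probe stood above background in those animals too. The signal does not tell a low transcript from a probe that matches it poorly. A hypothesis was that such probes match the RNA of some animals only, as a sequence variant in an outbred strain would give. The number of features whose arrays parted by animal with a gap of at least 1.5 log2 was 3. In 20 regroupings of the slices the median was 0.5, and the highest also gave 3. The regroupings reuse the same arrays, so one that keeps the high and low slices apart counts the same genes again. The number itself therefore neither bears the hypothesis out nor speaks against it. FR minus nonFR was 0.063 for Rps9 and -0.11 for Tac3.

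A second hypothesis was that genes of a list vary together less in FR areas. The mean correlation between members, on values centred by animal, was 0.14 in FR and 0.13 in nonFR areas over 39 lists and lower in FR areas in 17 of them. The difference was 0.011, and 21 of the 32 exchanges of the labels lay as far from 0. In 5 of 6 animals the centring ties the means of both kinds of area to each other, which pulls the difference towards 0, so the hypothesis stays open.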
